A study of Mus musculus with 219 samples.

How the data were processed

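The series holds total RNA sequencing of left prefrontal cortex from mice. Per the labels, RNA was taken with an AllPrep kit, ribosomal RNA was removed with a NEBNext depletion kit, and directional NEBNext Ultra II libraries were run on a NovaSeq. The first part is a daily atlas of wild-type mice kept in home cages under 12 h of light and 12 h of dark and collected at 8 times of day, given as zeitgeber time (ZT, hours after lights on). It has 92 libraries, with 6 per sex and time except 5 at ZT18 and ZT21. The other part holds mice collected at ZT6 after entrainment in light-controlled incubators to 12 h light and 12 h dark (12:12) or to 11 h light and 11 h dark (11:11). One set of these mice had been in indirect calorimetry chambers and was collected in constant darkness. The other had been given running wheels and was collected in the light cycle. Each set was divided by sex and by 4 genotypes, written WT/WT, HET/WT (heterozygous for the Snord116 deletion), WT/TG (carrying the transgene that the labels write Ctg) and HET/TG (both).

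Per the labels there were 4 animals in each combination of set, sex, light cycle and genotype, except 3 in the WT/TG males on 11:11 in the calorimetry set. One further sample, a running wheel male on 12:12 with the WT/TG genotype, had no column in the table used here and was not analysed here, which left 3 libraries in that group and 126 at ZT6. The written design had counted it. Groups were taken from the labels alone. Every column of both tables matched 1 sample by name and was used.

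The authors deposited 2 tables of whole-number read counts per gene, not normalized, with 55487 gene identifiers each. Per the submitters' processing notes, Trim Galore, STAR, SAMtools and limma were used with the mm10 build. Their versions, the counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. Genes that overlap on either strand can therefore share reads, which applies to Snhg14 with Ube3a and to Gm38393, which overlaps Snrpn and Snhg14. Ribosomal protein genes, haemoglobin genes and other families with near-identical copies or pseudogenes are uncertain for the same reason. Gene symbols, types and coordinates came from GENCODE mouse release 21 on the same genome build (1-based), in which 55227 of the identifiers were found and 260 were not.

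Each table was analysed separately in R 4.3.3. Genes were kept with the filterByExpr function of edgeR 4.0.16, which left 18841 genes at ZT6 and 17193 in the atlas. Library sizes were scaled by TMM, dispersions were estimated robustly, and each comparison was a quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. At ZT6 a single model had a mean for each group of animals, and contrasts averaged over the other factors with equal weight. The contrasts compared HET/WT, WT/TG and HET/TG with WT/WT, HET/TG with HET/WT, 11:11 with 12:12, calorimetry with running wheel, and males with females. Interactions asked whether the HET/WT effect differed by light cycle, sex or set and whether the light cycle effect or the sex difference differed by set. The HET/WT contrast was also taken in each of the 8 combinations of set, sex and light cycle, and the light cycle contrast in each set and sex. In the atlas, expression was modelled with sex and a cosine and sine of a 24 h period. Rhythm was the joint test of both terms, and the sex difference in rhythm was the joint test of their products with sex. Peak time and peak-to-trough fold came from the fitted curve, with 95% intervals. A fold change is a log2 difference ± its standard error, obtained from the fold change and the F statistic. Levels are given as CPM, the library sizes being scaled by TMM, as mean ± SD.

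The genes named in the text follow a rule that was fixed before the data were examined, as were the gene lists, the first group of alternatives and the contrasts, except that the light cycle contrast in each set and sex and the contrast of the sex difference between sets were added after the data were seen. The rule took, for each main comparison, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM over 0 and a full gene symbol, the 20 largest peak-to-trough folds of the rhythm, all members of the core clock and Prader-Willi region lists, and up to 4 members of each other list by smallest p. After the values were seen this was narrowed mechanically to the first 5 rises and falls, the first 10 rhythmic genes, the first 2 members per list, and all calls of comparisons with at most 10 calls. Gm44831, Gm38393, Gm32014 and Gm10800, with Gstp1, Xist and Mtln where a single group of mice is described, and Tmem72 where the rhythm is described, fall outside the first rule and were chosen after their values were seen. Some genes that the rule takes are not reported here.

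The 28 gene lists cover the core clock, immediate early genes, heat shock and temperature response, glucocorticoid response, the Prader-Willi region, other imprinted genes, mitochondrially encoded genes, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, mTOR and energy sensing, DNA methylation machinery, neuropeptides and prohormone processing, and cholesterol synthesis. Cell and region markers cover excitatory, inhibitory and striatal neurons, olfactory bulb, hypothalamus, thalamus, oligodendrocytes and their precursors, astrocytes, microglia, endothelial and mural cells, choroid plexus, meningeal fibroblasts and blood, and the last list holds X inactivation and Y-linked genes. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Lists were set against the rhythm by Fisher's exact test, since camera takes no test of 2 terms. Members past the threshold were also counted with p adjusted over the list alone.

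The alternatives listed first were RLE scaling, no expression filter, DESeq2 1.42.0, the replicate number as a block, leaving out each replicate number in turn, the series of library numbers as a block in the atlas, time as 8 levels, each sex or set alone, and tissue markers as covariates at ZT6. Further alternatives were chosen after seeing the data. They left out the library labelled HET/WT replicate 3 of the running wheel females on 11:11, the WT/TG library richest in nuclear ribosomal RNA, or all ribosomal and small RNA genes. Others added the slope of log2 CPM on log2 exonic length of each library as a covariate, added tissue markers as covariates in the atlas, together or 1 list at a time, or left out each HET/WT or WT/WT library in turn. No alternative scaling moved the median fold change of all genes by over 0.1.

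The procedure was tested on simulated counts with 200 changed genes, 100 at each fold. For the HET/WT contrast, with 18416 genes tested, 55% of genes changed 1.2-fold and 78% of those changed 1.5-fold were called. The same folds were called at 68% and 94% for the light cycle contrast over the same genes. For the interaction of genotype with light cycle, 64% of genes changed 1.5-fold and 78% of those changed 2-fold were called over the same genes. For the atlas rhythm, with 17025 genes tested, 63% at 1.2-fold and 85% at 1.5-fold were called. In a single HET/WT group of calorimetry males on 12:12, 49% at 1.5-fold and 65% at 2-fold were called.

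The position of each ZT6 library on the atlas clock was estimated from the 21 core clock genes rhythmic there. It was the shift (grid 0.05 h) where the atlas curves best matched the library's differences from the mean 12:12 library of its set and sex. That mean was assumed, untested, to stand at ZT6 of the atlas. Light cycles were compared by a two-sided permutation test with 100000 resamples, as was the difference between sets. The window searched, first 6 h on either side, was widened to the whole 24 h circle (circular means and differences) after the estimates gathered at its ends. The best single shift of the mean change of a set and sex was then found on the circle, with the share of the summed squared log2 change it accounts for and a 95% interval from 1000 bootstrap samples of the libraries.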

Results

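RNA was measured in left prefrontal cortex of 92 wild-type mice across the day and of 126 mice of 4 genotypes at ZT6. The wild-type atlas had 6 mice per sex at each of 8 times of day, with 5 at ZT18 and ZT21. Mice at ZT6 were grouped by set (calorimetry or running wheel), sex, light cycle (12:12 or 11:11) and genotype, with 4 libraries per group and 3 in 2 of the WT/TG male groups. Total counts per library, in mega-counts, were 15.1 ± 0.983 (range 13 to 17.7) in atlas females and 15.6 ± 1.1 (14.1 to 18.4) in atlas males. They were 17.9 ± 2.01 (14.4 to 22.9) in calorimetry females, 17.7 ± 4.04 (12.7 to 29.9) in calorimetry males, 17.2 ± 1.04 (15.5 to 19.3) in running wheel females and 18.3 ± 2.77 (13.6 to 24.1) in running wheel males. No pair of libraries of a group held the same values, and every pair differed by more than sampling noise, the lowest chi-square per gene being 3.52 in the atlas and 3.78 at ZT6.

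The targeted region was examined first. Snhg14 (ENSMUSG00000100826, minus strand of chromosome 7, 59307924 to 59975759) is the long paternally expressed transcript that hosts the Snord116 small nucleolar RNAs. It stood at 189.8 ± 28.1 CPM in WT/WT libraries (n = 32) and at 36.7 ± 24.9 CPM in those labelled HET/WT (n = 32). The transgene alone left 183.5 ± 20.9 CPM in WT/TG (n = 30), and HET/TG libraries held 33.8 ± 10.7 CPM (n = 32). Ndn (ENSMUSG00000033585, plus strand of chromosome 7, 62346569 to 62350262), another paternally expressed gene of the Prader-Willi region, went the other way. It was at 70.6 ± 9.73 CPM in WT/WT, 134.8 ± 19.4 CPM in HET/WT, 75.4 ± 10.2 CPM in WT/TG and 128 ± 12.6 CPM in HET/TG. The 17 annotated Snord116 genes, at 59861731 to 59904848 on chromosome 7, were scarcely captured, with 64 counts summed over WT/WT libraries, 1 over HET/WT, 54 over WT/TG and 5 over HET/TG.

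The library labelled HET/WT replicate 3 of the running wheel females on 11:11 went against its label. Its Snhg14 level was 167.3 CPM, where the other HET/WT libraries lay between 20.8 and 54.3 CPM and the WT/WT and WT/TG libraries between 115.9 and 280.6 CPM. Its Ndn level was 82.6 CPM, below the 102.3 to 175.7 CPM of the others with its label. It was kept under its label, and directions of the HET/WT comparison include it.

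**Figure D1:**
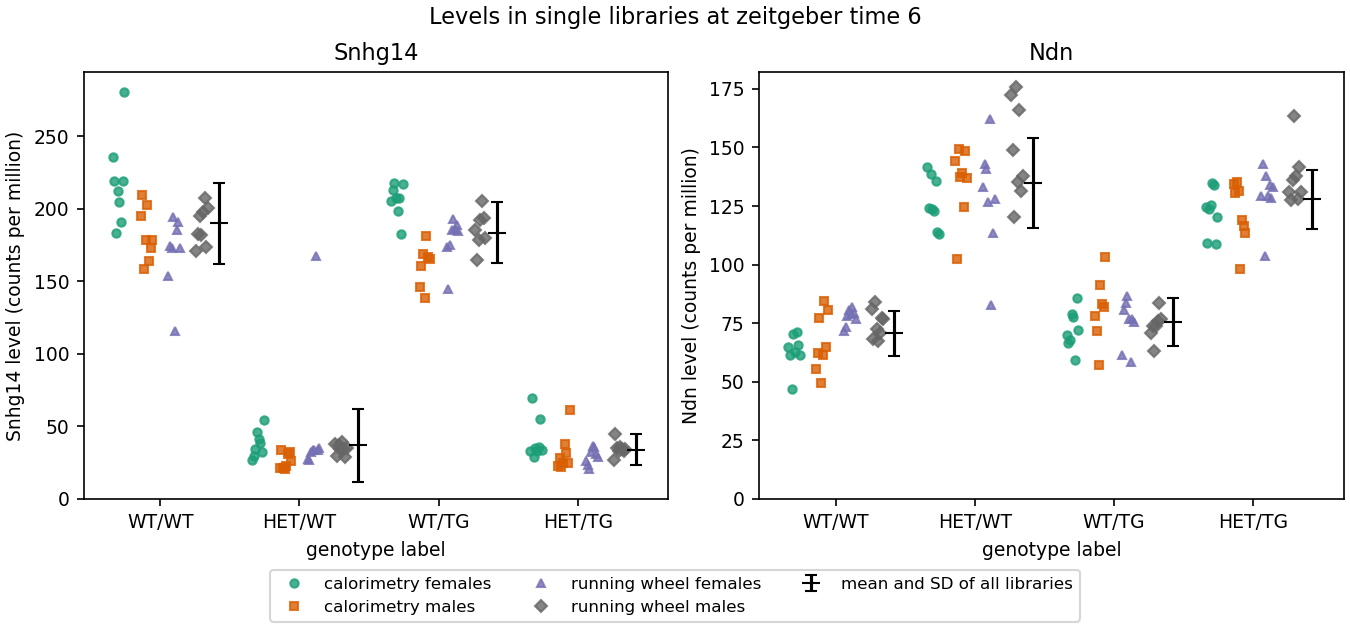
Levels of Snhg14 (left) and Ndn (right) in CPM on the vertical axis for each ZT6 library by genotype label, with symbols for set and sex and black bars for the mean and SD of all libraries of a genotype. The library labelled HET/WT at 167.3 CPM of Snhg14 stands apart from the other HET/WT libraries, which reach at most 54.3 CPM.

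The comparison of HET/WT with WT/WT asked what the Snord116 deletion changes in the cortex, averaged over set, sex and light cycle. Snhg14 was lower in the libraries labelled HET/WT (log2 fold change -2.42 ± 0.09, adjusted p = 7.14e-42), and Ndn, a growth-restraining MAGE family protein of neurons, was higher (0.93 ± 0.04, adjusted p = 2.59e-36). Rbm3, a cold-inducible RNA-binding protein, was lower (-0.27 ± 0.05, adjusted p = 0.01). Ctss, a microglial protease, was higher (0.16 ± 0.04, adjusted p = 0.0398). The 8 calls, 4 without replicate number 4, also included Gm38393 (-1.26 ± 0.06) and Gm44831, both in the Prader-Willi region, and Gm32014 on chromosome 9 (-0.60 ± 0.11). Gm44831, annotated at 59627688 to 59630676 inside Snhg14, had 0 counts in every HET/WT library except the one that went against its label, where it stood at 1 CPM.

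Other genes of the Prader-Willi region were measured without passing the test. Snrpn, which encodes a splicing protein, differed by 0.11 (adjusted p = 0.661), Ube3a, the maternally expressed ubiquitin ligase gene of Angelman syndrome, by -0.07 (adjusted p = 0.687), Magel2 by -0.10 (adjusted p = 0.964) and Mkrn3 by 0.40 (adjusted p = 0.745). Of the 10 region members tested, 1 rose and 1 fell, and 4 passed when adjusted over the list alone (fry adjusted p = 0.0269, and adjusted p = 0.704 with an estimated correlation). The circadian repressor Per2 differed by 0.03 (adjusted p = 0.977), and 0 of the 24 core clock genes passed in edgeR over all genes, with 0 adjusted over the list alone. The heat shock and temperature list had 1 of 23 members called, Rbm3, and 5 adjusted over the list alone, with a median of 0.08 and a camera adjusted p of 3.28e-05. Microglia markers had 0 of 11 called and 2 adjusted over the list alone (camera adjusted p = 0.000349), and striatal neuron markers 0 of 15 and 0 (median 0.28, camera adjusted p = 6.85e-05). With an estimated correlation each of these 3 lists had an adjusted p of 0.696. Over all genes 2 rose and 6 fell (1 and 6 with ribosomal and small RNA genes left out), and 1206 of 18841 had an unadjusted p under 0.05, where 942 would come by chance alone.

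Comparisons with the transgene asked what Ctg does alone and on the deletion. In WT/TG against WT/WT, N4bp2, a nucleotide kinase and endonuclease that binds Nedd4 (plus strand of chromosome 5, 65763521 to 65830108), was lower (-0.92 ± 0.08, adjusted p = 2.09e-16). Sdad1, a factor of ribosome assembly on the same chromosome (92284010 to 92310479), was lower by -0.61 ± 0.12 (adjusted p = 0.0187), and Gm10800, a gene model in repetitive sequence of chromosome 2 whose counts are uncertain, was higher (2.60 ± 0.31). Sdad1 no longer passed with any replicate number left out (-0.66 to -0.60). These 3 were the calls, with 803 genes at an unadjusted p under 0.05. Snhg14 differed by -0.05 and Ndn by 0.11, both with an adjusted p of 1, and Per2 by 0.22 with an adjusted p of 1.

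HET/TG libraries differed from WT/WT in 9 genes, 6 to 7 without a replicate number. Snhg14 (-2.51 ± 0.09) and Rbm3 (-0.26 ± 0.05) were lower, and Ndn was higher (0.86 ± 0.04). N4bp2 (-0.81 ± 0.08), Sdad1 (-0.58 ± 0.12), Zfand2a, a proteasome partner (-0.12 ± 0.02, adjusted p = 0.0175), Gm38393 and Gm44831 were lower too, and Gm10800 higher. Set directly against HET/WT, HET/TG differed only in N4bp2 (-0.89 ± 0.08, adjusted p = 2.31e-16) and Gm10800 (3.85 ± 0.38) among 18841 genes tested with edgeR. Sdad1 did not pass there (-0.53 ± 0.12, adjusted p = 0.134), and its calls, which share the WT/WT libraries, ended in HET/TG without replicate number 1, 3 or 4. Snhg14 differed by -0.09 (adjusted p = 0.874) and Ndn by -0.07 (adjusted p = 0.743) in that contrast. Cytosolic ribosomal proteins had 0 of 75 called and 0 adjusted over the list alone, with a camera adjusted p of 2.21e-15 downward and an adjusted p of 0.782 with an estimated correlation. Blood markers in HET/TG against WT/WT had 0 of 8 called and 4 adjusted over the list alone (camera adjusted p = 0.000206, and adjusted p = 0.325 with an estimated correlation).

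Whether light cycle, sex or set changes the deletion's effect was tested by interactions. The Snhg14 effect differed by 0.43 between light cycles (adjusted p = 0.639), by -0.43 between males and females (adjusted p = 0.808) and by -0.51 between calorimetry and running wheel (adjusted p = 1), each including the library labelled HET/WT that went against its label. In edgeR 0 genes passed for light cycle, 0 for sex and 0 for set, with 1331, 1051 and 812 genes at an unadjusted p under 0.05. DESeq2 called 3, 0 and 0, and edgeR without the expression filter 106, 83 and 97. In the interaction with light cycle, immediate early genes, which neurons switch on with activity, had 0 of 25 called and 11 adjusted over the list alone, with a median of 0.37. Camera gave an adjusted p of 7.31e-16 upward on 11:11, and the adjusted p was 0.211 with an estimated correlation. Mitochondrially encoded genes had 0 of 12 called and 2 adjusted over the list alone (camera adjusted p = 4.89e-10, and adjusted p = 0.211 with an estimated correlation).

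Within single groups of 4 against 4 mice, Snhg14 and Ndn were called in all 8 combinations, although running wheel females on 11:11 had 0 calls without HET/WT replicate 2. In calorimetry mice the Snhg14 fold changes were -2.41 in females on 11:11, -2.65 in females on 12:12, -2.65 in males on 11:11 and -2.98 in males on 12:12. In running wheel mice they were -1.26 in females on 11:11, the group with the library that went against its label, -2.49 in females on 12:12, -2.50 in males on 11:11 and -2.41 in males on 12:12. Running wheel males on 12:12 also had Gstp1, a glutathione transferase, higher (0.48), Mtln, a mitochondrial microprotein, higher (0.64) and Xist lower (-4.87). Xist, the RNA of X inactivation, was at 16.7 CPM in 1 WT/WT male of that group and at most 6.1 CPM in other males at ZT6. In all, 3 genes of running wheel males on 12:12 were higher and 4 lower, and by DESeq2 8 and 4. These 7 calls became 12 without HET/WT replicate 2, 40 without HET/WT replicate 4, 4 and 66 without replicate number 1 or 4 in both genotypes, and 82 without the expression filter. Calls numbered 4 and 4 in calorimetry females, 25 and 85 in calorimetry males, 3 and 4 in running wheel females and 4 and 7 in running wheel males, on 11:11 and 12:12 in turn. Leaving out 1 library moved the 25 to between 5 and 125 and the 85 to between 5 and 205, so these counts rest on single libraries.

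The light cycle comparison set 11:11 against 12:12 at the same nominal time of day. Plin4, a coat protein of lipid droplets, had the largest rise on 11:11 (1.2 ± 0.17, adjusted p = 1.51e-07), followed by Fmo2, a flavin monooxygenase (0.71 ± 0.10), Mir6236 (0.68 ± 0.21), Per2 (0.56 ± 0.07, adjusted p = 2.53e-08) and Mc4r, the melanocortin receptor that restrains feeding (0.55 ± 0.12). Plin4 was at -0.13 in running wheel mice alone. Mir6236 was at -0.02 in calorimetry mice alone, and its rise includes the WT/TG library rich in ribosomal RNA. The largest falls were Htr1d, a serotonin receptor (-0.56 ± 0.19, adjusted p = 0.0352), Dmkn, an epidermal secreted protein (-0.50 ± 0.13), Fam181a (-0.44 ± 0.11), Slc22a3, an organic cation transporter (-0.43 ± 0.13), and Klhl38 (-0.40 ± 0.10). In all, 2383 genes passed, 1412 higher and 971 lower on 11:11.

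Of 24 core clock genes, 13 rose and 1 fell (14 adjusted over the list alone, camera adjusted p = 1.29e-10, and adjusted p = 0.00745 with an estimated correlation). The repressors Ciart (0.41 ± 0.07), Per1 (0.31 ± 0.06), Per3 (0.22 ± 0.03) and Cry2 (0.13 ± 0.02) rose beside Per2, as did Bhlhe40 (0.28 ± 0.05) and Bhlhe41 (0.23 ± 0.03). The PAR-bZIP output factors Dbp (0.27 ± 0.05), Hlf (0.17 ± 0.02) and Tef (0.10 ± 0.02) rose, and the activator Arntl (BMAL1) fell (-0.14 ± 0.03). Nr1d1 (REV-ERB alpha) did not pass (0.08, adjusted p = 0.241).

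Of the heat shock and temperature list 18 of 23 rose (20 adjusted over the list alone, adjusted p = 0.0606 with an estimated correlation), among them the endoplasmic reticulum chaperones Hspa5 (0.28 ± 0.05) and Pdia4 (0.26 ± 0.04). Of the glucocorticoid response list 14 of 19 rose (14 adjusted over the list alone, adjusted p = 0.0514 with an estimated correlation), Errfi1 by 0.17. Immediate early genes rose in 7 of 25 cases (13 adjusted over the list alone, adjusted p = 0.502 with an estimated correlation), Egr1 by 0.33 and Nr4a3 by 0.27. Of 45 other imprinted genes 10 rose and 1 fell (13 adjusted over the list alone, adjusted p = 0.124 with an estimated correlation), with Grb10, an adaptor that restrains insulin signalling, at 0.13 and Ago2 at 0.10. The Prader-Willi list had 1 of 10 higher, Atp10a, a phospholipid flippase (0.28 ± 0.05, adjusted p = 2.70e-05), and 1 adjusted over the list alone (adjusted p = 0.72 with an estimated correlation).

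Among cytosolic ribosomal proteins 56 of 75 fell and 0 rose (61 adjusted over the list alone, camera adjusted p = 1.38e-36, and adjusted p = 0.0661 with an estimated correlation), with Rpl35 at -0.23 ± 0.04 and Rpl26 at -0.20 ± 0.03. Of 74 nuclear oxidative phosphorylation genes 26 fell and 1 rose (36 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation), with the respiratory chain subunits Ndufa8 at -0.14 and Cox6b1 at -0.13. Of 12 mitochondrially encoded genes 3 rose, mt-Nd4l by 0.64 ± 0.19 (9 adjusted over the list alone, adjusted p = 0.472 with an estimated correlation). In the mTOR and energy sensing list 8 of 28 rose and 2 fell (13 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation), the insulin pathway genes Igf1r and Irs2 by 0.15 and 0.21. DNA methylation genes rose in 3 of 20 cases (4 adjusted over the list alone, adjusted p = 0.472 with an estimated correlation), Dnmt1 by 0.09. Cholesterol synthesis genes fell in 4 of 23 cases (4 adjusted over the list alone, camera adjusted p = 0.158), Msmo1 by -0.06. Among neuropeptides and their processing genes 1 of 22 fell, Pcsk1n, an inhibitor of prohormone convertase (-0.11), with 0 adjusted over the list alone.

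Excitatory neuron markers rose in 4 of 14 cases (6 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation), Neurod6 by 0.17, and oligodendrocyte precursor markers in 3 of 7 (4 adjusted over the list alone, adjusted p = 0.0514 with an estimated correlation), Pdgfra by 0.08. Oligodendrocyte markers rose in 4 of 12 cases and fell in 1, with Ermn at 0.14 and Opalin at -0.27 ± 0.05. Endothelial and mural markers rose in 2 of 14 cases and fell in 2, microglia markers fell in 1 of 11 (Tyrobp, -0.20), meningeal markers rose in 1 of 10 (Aebp1, 0.14), and the haemoglobins Hbb-bs (-0.38 ± 0.06) and Hbb-bt (-0.31) were among 3 of 8 blood markers that fell (adjusted p = 0.238 with an estimated correlation). Adjusted over the list alone, these counted 5 oligodendrocyte, 4 endothelial and mural, 1 microglia, 1 meningeal and 3 blood genes. Inhibitory and striatal neuron, olfactory bulb, hypothalamic, thalamic, astrocyte, choroid plexus and sex-linked lists had 0 calls in edgeR and 0 adjusted over the list alone. With the length slope of each library as a covariate 1265 genes passed, in running wheel mice alone 36 passed, and with each replicate number left out in turn between 998 and 1815 passed.

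The light cycle difference was found mainly in calorimetry mice, which were collected in constant darkness. It called 2319 genes in calorimetry females (1261 higher, 1058 lower), 2544 in calorimetry males (1352 higher, 1192 lower), 52 in running wheel females (49 higher, 3 lower) and 0 in running wheel males. Under RLE scaling the split in calorimetry males was 1152 higher and 1574 lower, and by DESeq2 1242 higher and 1722 lower. In running wheel males 749 genes had an unadjusted p under 0.05 and DESeq2 called 1. Without the WT/TG library of running wheel females that was richest in ribosomal RNA their count was 11, DESeq2 called 215 there (181 higher, 34 lower), and leaving out each replicate number gave between 0 and 133. In calorimetry females the count was 1065 with the length slope as a covariate and between 570 and 2077 with a replicate number left out, and in calorimetry males between 1354 and 2530.

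Per2 stood at 57.2 ± 13.9 CPM on 11:11 and 24 ± 5.2 CPM on 12:12 in calorimetry females (n = 16 each), and at 37.1 ± 7.74 (n = 15) and 21.7 ± 5.15 CPM in calorimetry males. In running wheel mice it was 35.6 ± 9.39 and 28 ± 9.92 CPM in females and 31.3 ± 10.3 and 34.4 ± 9.51 CPM in males. Plin4 was at 13.5 ± 8.98 CPM on 11:11 and 1.84 ± 1.47 CPM on 12:12 in calorimetry females, and at 7.81 ± 4.64 and 1.76 ± 1.75 CPM in calorimetry males. The test of the difference between sets called 1003 genes, 516 with a more positive and 487 with a more negative light cycle effect in calorimetry, with 596 called under the length slope covariate and between 298 and 830 without a replicate number. Plin4 (2.65 ± 0.33, adjusted p = 4.03e-08), Fmo2 (1.07 ± 0.20), Per2 (0.90 ± 0.14, adjusted p = 1.94e-05), the death receptor Tnfrsf25 (0.84) and the signalling adaptor Dok3 (0.72) led the positive differences. Dsp (-1.84 ± 0.58), Lars2 (-1.54 ± 0.34), CT010467.1, Mir6236 (-1.41 ± 0.42) and Lct (-1.0) led the negative ones, with the WT/TG library at 40.3% ribosomal RNA kept.

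Among core clock genes the interaction was positive for 6 and negative for 1 of 24 (10 adjusted over the list alone, camera adjusted p = 9.1e-07, and adjusted p = 0.0763 with an estimated correlation). The positive ones were Per2, Cry1 (0.54 ± 0.07), Per3 (0.40 ± 0.06), Hlf (0.25 ± 0.05), Tef (0.17) and Cry2 (0.16), and the negative one was Nr1d1 (-0.41 ± 0.08). Cry1 rose by 0.55 in calorimetry females and 0.36 in calorimetry males, where running wheel mice had -0.06 and -0.11. Immediate early genes had 8 of 25 positive (17 adjusted over the list alone, adjusted p = 0.142 with an estimated correlation), Homer1 at 0.40 and Dusp6 at 0.32. Heat shock and temperature genes had 11 positive and 2 negative of 23 (16 adjusted over the list alone, adjusted p = 0.166 with an estimated correlation), the chaperone Pdia4 at 0.38 and the cold-inducible Cirbp at -0.47 ± 0.08. Ribosomal proteins had 48 of 75 negative (63 adjusted over the list alone, adjusted p = 0.0763 with an estimated correlation), Rps16 at -0.44 ± 0.07, and oxidative phosphorylation genes 27 negative and 1 positive of 74 (47 adjusted over the list alone, adjusted p = 0.0763 with an estimated correlation). Atp10a again stood out in the Prader-Willi list (0.45 ± 0.10, adjusted p = 0.00205).

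**Figure D2:**
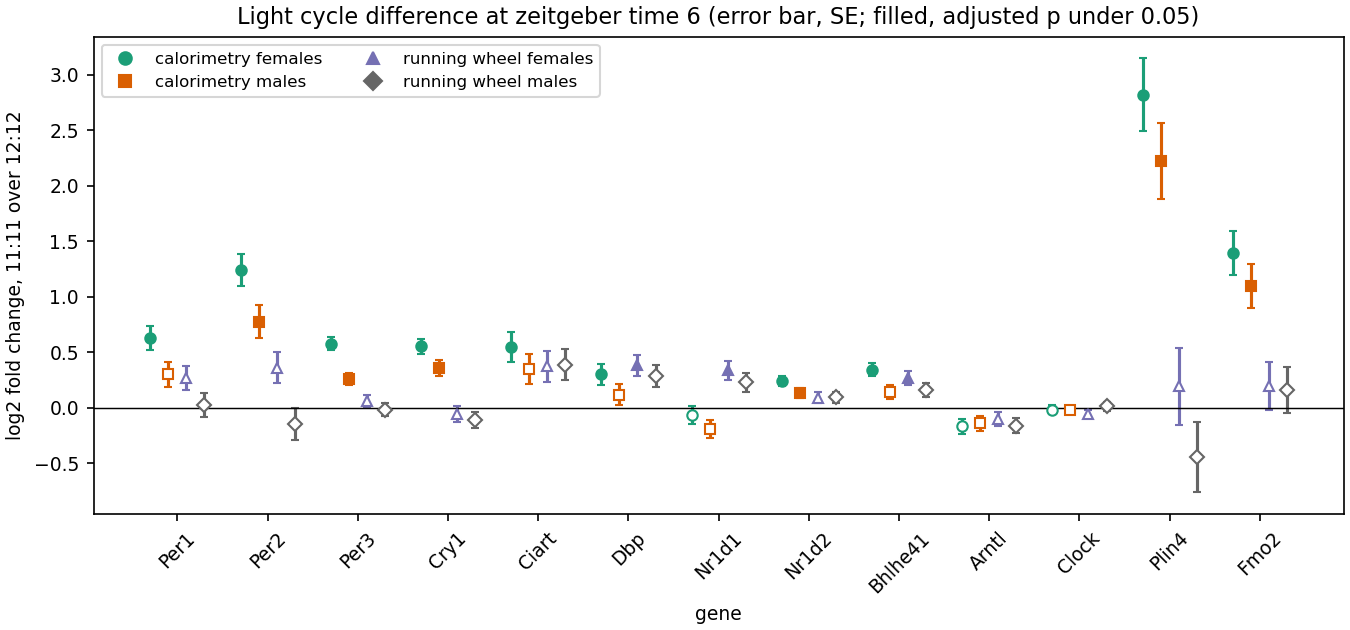
Log2 fold change of 11:11 over 12:12 on the vertical axis for core clock genes, Plin4 and Fmo2 on the horizontal axis, in each set and sex, with SE as error bars and filled symbols for an adjusted p under 0.05. Per2 was higher on 11:11 by 1.24 in calorimetry females and 0.78 in calorimetry males, against 0.36 and -0.15 in running wheel females and males, which did not pass.

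The calorimetry and running wheel sets differed in housing, exercise and light at collection, and their comparison cannot part these from the handling of each set. Calorimetry libraries held more of the small cytoplasmic RNAs Rn7s2 (3.40 ± 0.17), Rny3 (3.31 ± 0.17), Rny1 (3.29 ± 0.19) and Rn7s1 (2.82 ± 0.16), and of the mitochondrial transfer RNA mt-Ti (2.89 ± 0.18). They held less of the choroid plexus genes Mfrp (-2.05 ± 0.80), Slc4a5 (-1.89 ± 0.60), Tmem72 (-1.68 ± 0.60), Cldn2 (-1.61 ± 0.51) and Ttr, the thyroxine carrier of cerebrospinal fluid (-1.44 ± 0.51, adjusted p = 0.0107). In all 11713 genes passed, 5516 higher and 6197 lower in calorimetry, and 6544 with the length slope of each library as a covariate. In both sexes separately 2407 genes were higher (1270 for independent lists) and 2149 lower (1382 for independent lists), while 886 genes higher in calorimetry females were lower in calorimetry males and 733 lower in females were higher in males.

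Core clock genes went both ways, with 10 higher and 10 lower of 24 (20 adjusted over the list alone, adjusted p = 0.84 with an estimated correlation). Dbp (0.81 ± 0.05), Bhlhe41 (0.67 ± 0.03), Ciart (0.42), Cry1 (0.32) and Nr1d2 (0.29) were higher in calorimetry, and Nfil3 (-0.70 ± 0.05), Arntl (-0.47 ± 0.03) and Per1 (-0.33 ± 0.06) lower. Immediate early genes were higher in 4 and lower in 12 of 25 cases (17 adjusted over the list alone), with Nptx2 at -0.58 and Fosl2 at -0.78. Heat shock and temperature genes were higher in 5 and lower in 14 of 23 (19 adjusted over the list alone), although Hspe1 (1.08) and Rbm3 (0.79 ± 0.04) were higher. Glucocorticoid response genes were higher in 3 and lower in 8 of 19 (11 adjusted over the list alone), Cdkn1a at -1.02. In the Prader-Willi list, with 2 higher and 4 lower of 10 (7 adjusted over the list alone), Snrpn (0.39 ± 0.03) was higher and Magel2 (-0.50 ± 0.15) and Ndn (-0.10) lower, while Snhg14 did not pass (-0.01, adjusted p = 0.87, and 0.39 with the length slope as a covariate). Other imprinted genes were lower in 27 and higher in 8 of 45 (36 adjusted over the list alone, adjusted p = 0.133 with an estimated correlation), Peg3 at -0.35 and Igf2r at -0.38.

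Ribosomal proteins were higher in 74 of 75 cases (74 adjusted over the list alone, median 0.81, camera adjusted p = 1.02e-73, and adjusted p = 0.0058 with an estimated correlation), Rps28 by 1.37 ± 0.03. Nuclear oxidative phosphorylation genes were higher in 73 of 74 (73 adjusted over the list alone, adjusted p = 0.00328 with an estimated correlation), Uqcr10 by 1.00 and Uqcrq by 0.98 ± 0.03. Mitochondrially encoded genes went 6 up and 4 down of 12 (10 adjusted over the list alone), mt-Co2 by 1.80. The mTOR list had 5 higher and 19 lower of 28 (24 adjusted over the list alone, adjusted p = 0.444 with an estimated correlation), Mtor at -0.28, and cholesterol synthesis 3 higher and 15 lower of 23 (18 adjusted over the list alone, adjusted p = 0.57 with an estimated correlation). DNA methylation genes had 4 higher and 11 lower of 20 (15 adjusted over the list alone), Dnmt3a at -0.25, and neuropeptide genes 10 higher and 7 lower of 22 (17 adjusted over the list alone), Pcsk1n at 0.60.

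Markers of other cells differed between the sets as well. Striatal markers were lower in calorimetry in 14 of 15 cases (adjusted p = 0.84 with an estimated correlation), Scn4b at -0.48, and choroid plexus markers in 8 of 10 (adjusted p = 0.881 with an estimated correlation), Kl at -1.15. Oligodendrocyte markers were higher in 9 and lower in 1 of 12 (adjusted p = 0.776 with an estimated correlation), Mbp at 0.49 and Mobp at 0.68, precursor markers higher in 1 and lower in 4 of 7, Cspg4 at -0.46. Microglia markers were higher in 8 and lower in 2 of 11, Tyrobp at 0.81, and blood markers higher in 5 of 8 (adjusted p = 0.369 with an estimated correlation), Hba-a2 at 1.25. Hypothalamic markers were higher in 3 of 5, the peptide genes Pmch at 1.67 and Avp at 1.53. Counts of the remaining lists, higher and lower, were 1 and 7 of 14 excitatory, 4 and 5 of 14 inhibitory, 1 and 1 of 6 olfactory bulb, 1 and 2 of 9 thalamic, 5 and 2 of 10 astrocyte, 6 and 5 of 14 endothelial and mural, 3 and 5 of 10 meningeal and 0 and 0 of 5 sex-linked genes. Adjusted over the list alone, calls numbered 14 striatal, 9 choroid plexus, 10 oligodendrocyte, 5 precursor, 10 microglia, 5 blood and 3 hypothalamic markers. For the remaining lists, in the order just given, they numbered 8, 9, 2, 3, 7, 11, 8 and 0. Olfactory bulb markers had a median of 0.12, although camera pointed downward (adjusted p = 0.864).

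Male and female mice were compared at ZT6. The Y-linked genes Ddx3y (11.57 ± 0.11), Uty (11.02), Kdm5d (10.97) and Eif2s3y (10.70) were higher in males, and Xist was lower (-11.44 ± 0.18). They match the sex labels in every library, with Ddx3y at 26.6 to 116.2 CPM in males and 0 to 0.47 CPM in females. Males also had more Rny3 (3.18) and less of the choroid plexus genes Prlr and Tmem72 (both -1.21). Choroid plexus log2 CPM averaged 0.93 and 0.05 in calorimetry females and males, 1.28 and 1.37 in running wheel ones. In all 10948 genes passed, 5208 higher and 5740 lower in males, and 3960 with the length slope as a covariate.

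Ribosomal proteins were higher in males in 74 of 75 cases (74 adjusted over the list alone, median 0.70, adjusted p = 0.00246 with an estimated correlation), Rps28 by 1.22 ± 0.03, and oxidative phosphorylation genes in 72 of 74 (72 adjusted over the list alone, adjusted p = 0.000813 with an estimated correlation), Uqcr10 by 0.93. The sex difference itself differed by set in 9764 genes, 4278 with a more positive and 5486 with a more negative value in calorimetry. It called 11887 genes in calorimetry (5456 higher, 6431 lower) and 6371 in running wheel mice (3380 higher, 2991 lower). Rps16, a ribosomal protein gene, stood in calorimetry males at 186.8 CPM on 11:11 and 245.4 CPM on 12:12, and in calorimetry females at 67 and 87.6 CPM. In running wheel mice it stood at 61.5 and 62.3 CPM in females and 75.2 and 69.4 CPM in males. The slope of log2 CPM on log2 exonic length, lower where short transcripts take a larger share, averaged 0.918 in calorimetry males, 1.06 in calorimetry females, 1.13 in running wheel females and 1.06 in running wheel males. Nuclear ribosomal RNA took 2.62% ± 2.19 of counts in calorimetry males, 0.396% ± 0.253 in calorimetry females, 1.97% ± 7.0 in running wheel females (0.731% ± 0.323 without the WT/TG library at 40.3%) and 0.25% ± 0.189 in running wheel males, and small RNA 0.732%, 0.40%, 0.499% and 0.352% in the same order.

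Core clock genes were higher in males in 4 and lower in 9 of 24 cases (13 adjusted over the list alone), Bhlhe41 at 0.23 and Fbxl21 at -0.26. With the length slope as a covariate Per3 (0.10), Clock (0.10), Arntl (0.035), Rora (0.13), Hlf (0.23) and Rorb (0.036) turned to higher and Dbp to -0.0032. In running wheel mice alone Clock (0.0048), Arntl (0.19) and Tef (-0.10) turned, and in calorimetry mice alone Per1 (-0.20) and Nfil3 (-0.18). Heat shock and temperature genes were higher in 10 and lower in 5 of 23, Hspe1 at 0.91, immediate early genes higher in 9 and lower in 1 of 25, Gadd45b at 0.33, and glucocorticoid response genes higher in 5 and lower in 3 of 19, with the receptor gene Nr3c1 at -0.22. Other imprinted genes were higher in 11 and lower in 20 of 45 (adjusted p = 0.215 with an estimated correlation), Peg3 at -0.31 and Igf2r at -0.37, and in the Prader-Willi list, with 3 higher and 3 lower of 10, Snrpn was higher (0.29 ± 0.03) and Ube3a lower (-0.23 ± 0.02), the last turning to 0.06 with the length slope as a covariate. The mTOR list had 4 higher and 18 lower of 28 (adjusted p = 0.171 with an estimated correlation), Mtor at -0.28. Oligodendrocyte precursor markers were lower in 5 of 7 (adjusted p = 0.111 with an estimated correlation), Vcan at -0.45, striatal markers lower in 12 of 15 (adjusted p = 0.896 with an estimated correlation), Pde10a at -0.66, and blood markers higher in 5 of 8 (adjusted p = 0.179 with an estimated correlation). Hypothalamic markers were higher in 4 of 5, Pomc at 0.69 and Trh at 0.68, and neuropeptide genes higher in 13 and lower in 4 of 22, Pcsk1n at 0.77. Adjusted over the list alone, calls numbered 15 heat shock and temperature, 7 immediate early, 8 glucocorticoid response, 31 imprinted, 6 Prader-Willi, 23 mTOR, 5 precursor, 13 striatal, 5 blood, 4 hypothalamic and 18 neuropeptide genes.

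In the atlas, which asked how the wild-type cortex changes over the day, 7117 of 17193 genes were rhythmic, and 8543 had an unadjusted p under 0.05. Plin4 had the largest daily swing, 4.81-fold (95% interval 3.42 to 6.76) with a peak at ZT15.8 ± 0.42, from 1.68 ± 0.75 CPM at ZT6 to 11.8 ± 3.92 CPM at ZT15 (n = 12). Next came Ndst4, a heparan sulfate enzyme (4.52-fold, ZT1.73), Dsp (3.81-fold, ZT1.12) and the repressor Ciart (3.42-fold, 95% interval 3.1 to 3.79, ZT12.1 ± 0.16). The activity genes Egr2 (3.38-fold) and Arc (3.37-fold) had fitted peaks at ZT18.8 and ZT18.6, but their highest means were at ZT0, Egr2 with 6.73 ± 1.82 CPM against 6.38 ± 2.56 CPM at ZT18 and Arc with 348.9 ± 131 CPM against 276.7 ± 91.9 CPM. Fmo2 peaked in the dark phase (3.17-fold, ZT15). The orphan receptor gene Gpr101 (3.19-fold, ZT1.69), the lactase gene Lct (2.80-fold, ZT1.85) and the choroid plexus marker Kl (klotho; 2.85-fold, ZT0.306) had fitted peaks shortly after lights on. Mice differed widely in these, with Ndst4 at 13.2 ± 9.85 CPM, Dsp at 7.78 ± 7.94 CPM, Gpr101 at 2.61 ± 3.54 CPM and Lct at 9.16 ± 8.79 CPM at ZT3 and Kl at 17 ± 17.9 CPM at ZT0. The choroid plexus markers Prlr (8.41 ± 11.1 CPM at ZT3) and Tmem72 (4.61 ± 5.76 CPM at ZT0) and the olfactory bulb marker Cdhr1 (4.59 ± 5.14 CPM at ZT3) were highest and as variable at the same times. The median fold of rhythmic genes was 1.14, with 414 over 1.5-fold and 56 over 2-fold.

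Of 24 core clock genes 21 were rhythmic (22 adjusted over the list alone, Fisher adjusted p = 4.67e-05). Nr1d1 peaked first (ZT10.3, 1.94-fold), followed by Dbp (ZT12, 2.65-fold), Bhlhe41 (ZT12.4, 1.64-fold), Nr1d2 (ZT13.5), Per3 (ZT14.2, 1.51-fold), Tef (ZT14.9), Hlf (ZT15.3), Per1 (ZT15.5, 1.78-fold), Bhlhe40 (ZT16.5), Per2 (ZT16.7, 2.55-fold) and Cry1 (ZT18, 1.71-fold). The activators Clock (ZT23.6, 1.12-fold), Arntl (ZT23.9, 1.54-fold) and Npas2 (ZT0.214, 1.13-fold) peaked at the start of the light phase, with the repressor Nfil3 (ZT23.7, 1.59-fold). Dbp moved from 37.1 CPM at ZT0 to 99 ± 8.18 CPM at ZT12, and Per2 from 19.9 ± 1.78 CPM at ZT6 to 62.3 ± 6.06 CPM at ZT15. Fbxl21 did not pass (adjusted p = 0.603).

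**Figure D3:**
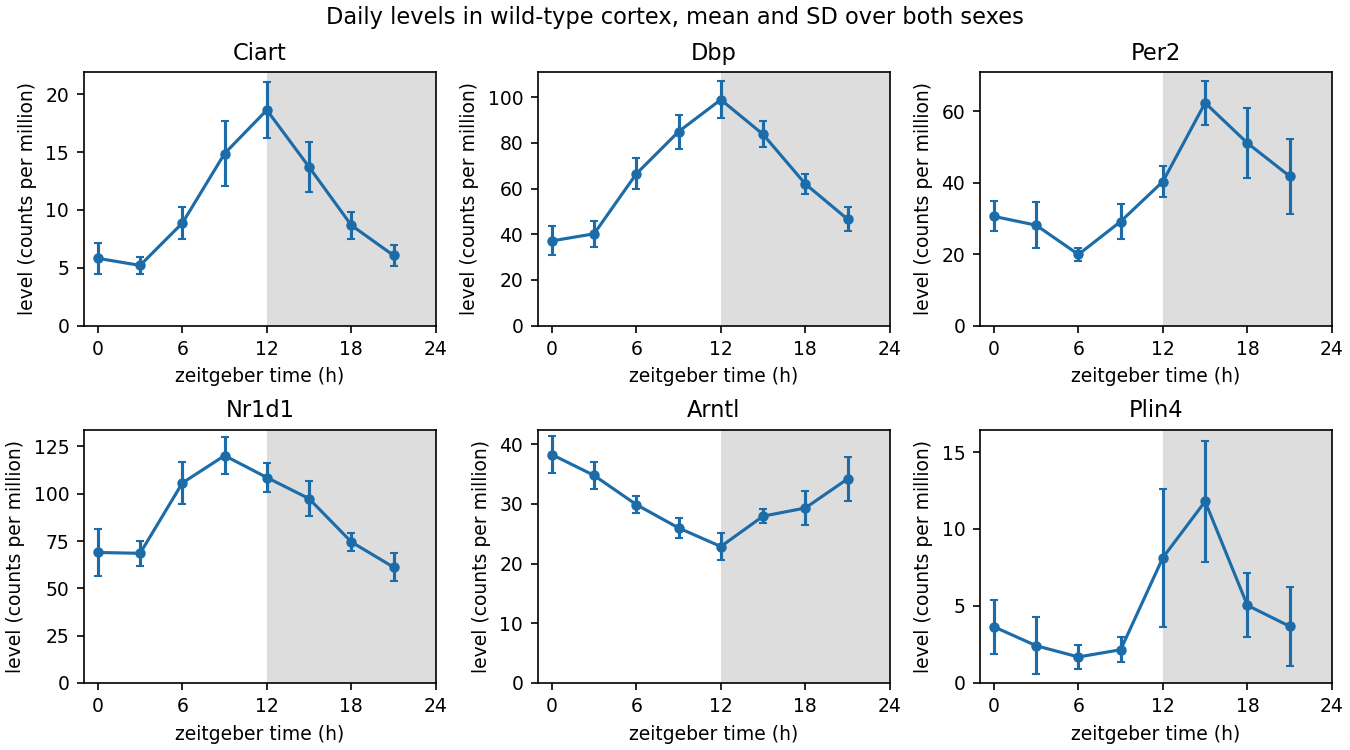
Levels in CPM on the vertical axis of 6 rhythmic genes against zeitgeber time in hours on the horizontal axis, as mean and SD over both sexes (n = 12, and 10 at ZT18 and ZT21), with the dark phase shaded. Per2 rose from 19.9 CPM at ZT6 to 62.3 CPM at ZT15, and Plin4 from 1.68 to 11.8 CPM between the same times.

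Rhythm was frequent in stress and activity lists. All 23 heat shock and temperature genes passed (Fisher adjusted p = 4.24e-08, mean peak ZT20.4), with Cirbp at ZT9.46 (1.61-fold) and the chaperone Dnajb1 at ZT18.5 (1.34-fold). Immediate early genes passed in 22 of 25 cases (Fisher adjusted p = 3.2e-05, mean peak ZT19.4), Egr1 at ZT18.5 (2.12-fold), and glucocorticoid response genes in 18 of 20 (Fisher adjusted p = 4.96e-05, mean peak ZT15.1), Tsc22d3 at ZT15.2 (1.54-fold). Microglia markers passed in 10 of 11 (Fisher adjusted p = 0.00404), Cx3cr1 at ZT3.49 (1.2-fold), mTOR and energy sensing genes in 19 of 28 (Fisher adjusted p = 0.0194), with Prkab1, a subunit of the energy sensor AMPK, at ZT8.11 (1.42-fold), and thalamic markers in 8 of 9 (Fisher adjusted p = 0.0171). Rhythm was less frequent than over all genes among oxidative phosphorylation genes, 10 of 74 (Fisher adjusted p = 4.34e-06), and striatal markers, 0 of 15 (Fisher adjusted p = 0.00172). Ribosomal proteins passed in 30 of 74 (Fisher adjusted p = 0.976).

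Rhythmic members numbered 24 of 45 among other imprinted genes, with Peg3 at ZT18.3 (1.16-fold), and 2 of 10 in the Prader-Willi list, Atp10a at ZT15.9 (1.41-fold) and Ube3a with a 1.05-fold swing (adjusted p = 0.0466). Snhg14 did not pass (1.06-fold, adjusted p = 0.0547). Cholesterol synthesis had 11 of 23, with Insig1, which restrains it, at ZT8.74 (1.28-fold) and Lss at ZT10.1 (1.2-fold), and DNA methylation 10 of 20, Gadd45a at ZT18.9 (1.80-fold). Neuropeptide genes had 8 of 21, the prohormone convertase gene Pcsk1 at ZT18.8 (1.32-fold), and mitochondrially encoded genes 4 of 13, mt-Nd1 at ZT6.65 (1.12-fold). Oligodendrocyte markers had 7 of 12, with Opalin at ZT6.53 (1.70-fold) and Mog at ZT10.3 (1.29-fold), precursor markers 2 of 7, Gpr17 at ZT19.8 (1.39-fold), and astrocyte markers 6 of 10, the water channel gene Aqp4 at ZT2.38 (1.18-fold). Endothelial and mural markers had 10 of 14 (Fisher adjusted p = 0.0735), with the tight junction gene Cldn5 at ZT23.5 (1.55-fold), choroid plexus 4 of 10, Prlr at ZT22.9 (2.78-fold), and meningeal fibroblasts 4 of 10. The remaining lists had 8 of 14 excitatory, 3 of 14 inhibitory, 5 of 6 olfactory bulb, 2 of 3 hypothalamic, 0 of 8 blood and 1 of 5 sex-linked genes. Adjusted over the list alone, counts that differed from these were 25 imprinted, 1 Prader-Willi, 2 mitochondrially encoded, 3 oxidative phosphorylation, 21 mTOR, 1 inhibitory, 3 hypothalamic, 9 oligodendrocyte, 11 microglia, 12 endothelial and mural, 6 choroid plexus and 0 sex-linked genes.

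The daily pattern differed between the sexes in 13 genes, with 1334 at an unadjusted p under 0.05 and 25 called by DESeq2. St18, a zinc finger factor of oligodendrocytes, swung 1.78-fold in males with a peak at ZT1.76 and 1.18-fold in females with a peak at ZT9.7 (adjusted p = 0.000437). Ptgs2, the inducible cyclooxygenase, peaked at ZT0.468 in males (1.47-fold) and ZT19.6 in females (adjusted p = 0.0305). Neurod6, a factor of cortical projection neurons, peaked at ZT23.9 in males and ZT18.8 in females (1.46-fold), and the repressor Bcl6 at ZT22.1 (1.27-fold) and ZT16.8 (1.38-fold). Golm1 swung 1.5-fold in males and 1.10-fold in females, and Cpm, a carboxypeptidase, 1.09-fold and 1.57-fold. Xist, which swung 3.23-fold in males and 1.04-fold in females, is near the floor in males. Spns2, Utrn, Polr3b and Nbeal1 were also called, each with a swing of at most 1.23-fold in either sex, and the remaining 2 calls were genes with clone names. No core clock gene was called (Arntl adjusted p = 0.236), and leaving out 1 replicate number moved the 13 to between 0 and 22.

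Male and female wild-type mice of the atlas differed in 7069 genes, 3617 higher and 3452 lower in males. Besides Uty (8.72), Kdm5d (8.69), Ddx3y (8.50), Eif2s3y (8.40) and Xist (-7.40 ± 0.18), the largest differences were a rise of C1ql2, a synaptic C1q-like protein (2.12 ± 0.28), and falls of Serpina9 (-2.69 ± 0.26), the forebrain factor Six3 (-2.59 ± 0.27), Drd2, the dopamine receptor of striatal indirect pathway neurons (-2.52 ± 0.25, adjusted p = 4.45e-14), and Rxrg (-2.40 ± 0.21). All 15 striatal markers were lower in males (15 adjusted over the list alone, median -1.57, camera adjusted p = 2.37e-16, and adjusted p = 0.136 with an estimated correlation). They include the peptide genes Penk (-1.86 ± 0.18) and Tac1 (-1.39 ± 0.13). The mean log2 CPM of the striatal markers was 5.25 ± 0.922 in females (n = 46) and 3.70 ± 0.618 in males (n = 46). With oligodendrocyte and striatal marker means as covariates 2086 genes passed, as the median size of 7050 called differences outside these lists went from 0.13 to 0.0825 and the median SE from 0.031 to 0.041.

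Ribosomal proteins were higher in males in 71 and lower in 1 of 74 cases (72 adjusted over the list alone, median 0.12, adjusted p = 0.136 with an estimated correlation), Rps15a by 0.17, oxidative phosphorylation genes higher in 46 of 74 (52 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation) and mitochondrially encoded genes lower in 9 of 13 (10 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation), mt-Cytb by -0.25. Cholesterol synthesis genes were lower in 18 and higher in 1 of 23 (19 adjusted over the list alone, adjusted p = 0.136 with an estimated correlation), Hmgcs1 at -0.17. Core clock genes were higher in 14 and lower in 5 of 24 (20 adjusted over the list alone, adjusted p = 0.616 with an estimated correlation), Rora at 0.21 and Fbxl21 at -0.42, while Dbp (0.012), Nr1d1 (-0.013) and Nfil3 (-0.078) turned with those covariates. The neutrophil genes Lcn2 (2.91) and S100a9 (1.01) and all 8 blood markers were higher in males (8 adjusted over the list alone, adjusted p = 0.481 with an estimated correlation), and the astrocyte gene Gfap was higher (0.50) among 6 of 10 astrocyte markers (8 adjusted over the list alone). Olfactory bulb markers were lower in 3 of 6 (3 adjusted over the list alone), Th at -0.71, and the layer marker Syt6 was lower (-0.78). Over the 17128 genes tested in all 3 sets of mice, 680 were higher in males in each set, where independent lists give 211.3, and 407 were lower, where they give 208.9. Of these, 28 and 20 lay on the X chromosome.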

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

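The tests of a wrong label, of a swap of libraries and of the library preparation set, the interaction of sex with set, the length slope covariate, the tissue covariates in the atlas and their effect on ribosomal protein genes were chosen after results were seen.

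The sex difference at ZT6 differed between calorimetry and running wheel mice in 9764 genes by the interaction test, and of 75 ribosomal protein genes 74 were higher in calorimetry and 74 in males. With the length slope as a covariate their medians were 0.61 between the sets (0.81 without it) and 0.49 between the sexes (0.70). In calorimetry mice the sex median was 0.71 (1.03). The slope follows set and sex, so these leave a gene length trend as the whole cause open. Such a trend may account for much of the sex difference in running wheel mice (0.12 from 0.29). That covariate brought calls between the sets from 11713 to 6544 and between the sexes from 10948 to 3960. Oligodendrocyte and striatal tissue as the whole cause is argued against by the medians with these markers as covariates, 0.85 between the sets, 0.72 between the sexes and 0.71 for the sex difference by set (from 0.81, 0.70 and 0.70), while the 10043 genes called between the sets with them cover all genes and decide nothing here. The interaction called 51.8% of the genes tested, as libraries prepared apart for each set and sex may give, and since such a preparation would coincide with set and sex, it and the biology of housing and sex cannot be told apart, with housing, exercise and light at collection open and not tested apart.

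The library labelled HET/WT replicate 3 of the running wheel females on 11:11 stood out from its group with Snhg14 at 167.3 CPM, where the other 3 lay between 26.4 and 35 CPM. A wrong label on this library may account for it, since 4 of 4 measures of the region (Snhg14, Ndn, Gm38393 and Gm44831) lay within the range of WT/WT and WT/TG libraries. A swap with a WT/WT or WT/TG library of the same group of mice is argued against, as 0 of those libraries had the Snhg14 level of the deletion. No biological explanation was tested.

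The atlas sex difference included all 15 striatal markers, lower in males by a median of -1.57. Striatal tissue taken along with the cortex in different amounts may account for part of it, but as the whole cause it is argued against outside the marker lists, where the median size of 7050 called differences stayed at 0.086 with the striatal marker mean as a covariate, from 0.13. The 2086 calls with striatal and oligodendrocyte means as covariates, from 7069, decide nothing, since the striatal mean differs between the sexes and widened the errors. The 7220 genes called with the series of library numbers as a block decide nothing, as the series was laid out alike in both sexes, while the letter of the library names follows sex, so that preparation of the libraries and sex cannot be told apart. A sex difference in these neurons themselves stays open and was not tested.

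Single libraries stood apart from a group of 4 to 6 in 9 of 138 groups and measures tested, and chance gives about 1 in 20. Snhg14 was at 220.4 CPM in replicate 3 of the atlas males at ZT15 (others 178.4 to 189.1), at 232.1 CPM in replicate 5 of those at ZT18 (167.7 to 183.9) and at 32.2 CPM in HET/WT replicate 4 of the calorimetry males on 12:12 (20.8 to 21.3). Ndn was at 89.1 CPM in replicate 6 of the atlas females at ZT0 (54.2 to 67.2), at 95.5 CPM in replicate 1 of the males at ZT0 (57.2 to 71.2) and at 163.4 CPM in HET/TG replicate 2 of the running wheel males on 11:11 (128 to 131.1). The share of nuclear ribosomal RNA was 0.833% in WT/TG replicate 3 of the calorimetry females on 11:11 (0.204% to 0.305%) and 40.3% in WT/TG replicate 1 of the running wheel females on 11:11 (0.355% to 1.35%).

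The light cycle effect differed between calorimetry and running wheel mice in 1003 genes by the interaction test, and among core clock genes by 0.90 for Per2, 0.54 for Cry1, 0.40 for Per3, 0.25 for Hlf, 0.17 for Tef, 0.16 for Cry2 and -0.41 for Nr1d1. The daily pattern differed between the sexes in 13 atlas genes by the interaction test.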

How the results depend on the processing

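Among the alternatives of this part, the length slope covariate, tissue marker covariates in the atlas (also 1 list at a time), and leaving out the library labelled HET/WT that went against its label, the WT/TG library rich in ribosomal RNA, the ribosomal and small RNA genes or single HET/WT and WT/WT libraries were chosen after the results were seen.

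Of 11288 values of named genes under other settings, 10548 kept their side of the threshold and 628 no longer passed. A further 56 newly passed and 56, in 47 results, turned. Turns were not counted for rhythm or genes never passing. Passing was lost most often in running wheel mice alone (79), with tissue markers (71) and with the length slope (69). Snord116 and other genes near the floor have few counts, and no setting adds reads. Where no cause is named for a change in this part, the cause was not tested.

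Without the expression filter more genes were tested and weakly measured ones entered. Calls were then 107 for HET/WT, 76 for WT/TG and 84 for HET/TG against WT/WT, 119 for HET/TG against HET/WT, and 106, 83 and 97 for the HET/WT effect by light cycle, sex and set. Within groups, HET/WT calls were 50 and 109 in calorimetry females on 11:11 and 12:12, 179 and 266 in calorimetry males, 129 and 42 in running wheel females and 93 and 82 in running wheel males. Light cycle calls were 274 in running wheel females and 108 in running wheel males.

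DESeq2 called 6 genes for WT/TG, 3 for the HET/WT effect by light cycle, 60 and 168 for HET/WT in calorimetry males on 11:11 and 12:12, 12 in running wheel males on 12:12, 215 and 1 for light cycle in running wheel females and males, and 25 for the sex difference in rhythm. The cause was not tested. Calorimetry mice alone gave 5 calls for HET/WT and 1 for WT/TG, and running wheel mice alone 5 for HET/WT and 36 for light cycle. In the atlas, males alone gave 4305 and females alone 3215 rhythmic genes.

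The length slope covariate gave 1265 calls for light cycle, 6544 for calorimetry against running wheel, 3960 for sex at ZT6, 596 for the light cycle effect by set, 1065 for light cycle in calorimetry females, and 64 and 139 for HET/WT in calorimetry males on 11:11 and 12:12. Tissue markers gave 42 and 232 in those males and 2086 for the atlas sex difference (2129 with striatal markers alone). Without the library rich in ribosomal RNA, light cycle calls in running wheel females were 11. The cause was not tested.

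With an estimated correlation the list tests kept 0 lists in each genotype comparison and each interaction, 1 for light cycle, 2 for calorimetry against running wheel, 3 for sex at ZT6 and 1 for sex in the atlas. By set and sex they kept 1 list for light cycle in calorimetry females and 0 in the other 3, 1 and 3 for calorimetry against running wheel in females and males, and 4 and 3 for sex in calorimetry and running wheel mice.

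Leaving out each replicate number, or each single HET/WT or WT/WT library, gave 4 to 9 calls for HET/WT, 2 for WT/TG, 6 to 7 for HET/TG and 2 to 3 for HET/TG against HET/WT. It gave 998 to 1815 for light cycle, 10701 to 10999 for calorimetry against running wheel, 9785 to 10200 for sex at ZT6, 0 for the HET/WT effect by light cycle, 0 to 1 for that by sex and by set, and 298 to 830 for the light cycle effect by set. Light cycle calls were 570 to 2077 in calorimetry females, 1354 to 2530 in calorimetry males, 0 to 133 in running wheel females and 0 in running wheel males. In the atlas it gave 5405 to 7080 rhythmic genes, 0 to 22 for the sex difference in rhythm and 5872 to 6962 for sex. HET/WT calls within groups were 4 and 3 to 4 in calorimetry females on 11:11 and 12:12, 5 to 125 and 5 to 380 in calorimetry males, 0 to 4 and 4 in running wheel females, and 4 to 5 and 4 to 66 in running wheel males.

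Single libraries decided several of these. In calorimetry males on 11:11 the 25 calls became 91, 48 and 11 without HET/WT replicate 1, 2 and 3, and 125, 39 and 5 without WT/WT replicate 1, 2 and 3. In those on 12:12 the 85 became 8 and 205 without HET/WT replicate 1 and 4, and 5 and 205 without WT/WT replicate 1 and 4. In running wheel females on 11:11 the 3 became 1, 0 and 1 without HET/WT replicate 1, 2 and 4, and 1 without WT/WT replicate 2.

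The replicate numbers share no source in the labels, and same-numbered libraries had a mean r of 0.00596 in the atlas and 0.0162 at ZT6 (lowest -0.317 and -0.255). The best match of a library had its own number in 19 of 92 atlas cases, where chance gives 15.3 (one-sided permutation p = 0.21), and in 47 of 126 cases at ZT6, where chance gives 31.5 (one-sided permutation p = 0.00592), a hint from the data of some sharing at ZT6. With the replicate block, calls were 8 for HET/WT, 3 for WT/TG, 9 for HET/TG, 2460 for light cycle, 11717 for calorimetry against running wheel, 10957 for sex at ZT6, 1022 for the light cycle effect by set, and 6993, 14 and 7069 for rhythm, its sex difference and sex in the atlas, and no count moved by over 1.5 times.

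Values that turned are log2 differences, and the cause was not tested. For light cycle in running wheel mice alone they were -0.13 for Plin4, -0.090 for Cry1, -0.00021 for Csnk1e, 0.032 for Insig1, -0.0089 for Gpr17 and -0.040 for Ly6c1, and in calorimetry mice alone -0.019 for Mir6236. For calorimetry against running wheel with the length slope they were 0.0033 for Npas2, 0.071 for Clock, 0.10 for Bhlhe40, 0.18 for Ube3a, 0.39 for Snhg14, 0.0023 for B230209E15Rik and -0.047 for Ramp3. For sex at ZT6 in running wheel mice alone they were 0.12 for Cldn2, 0.032 for Six3os1, 0.0048 for Clock, 0.19 for Arntl, -0.10 for Tef, -0.0059 for Rbm3, 0.0055 for Snhg14, 0.34 for A330076H08Rik, -0.057 for Ramp3, -0.089 for Mbp and -0.033 for Aldoc, and in calorimetry mice alone -0.20 for Per1, -0.18 for Nfil3 and -0.14 for mt-Co3. For sex at ZT6 with the length slope they were 0.10 for Per3, 0.10 for Clock, -0.0032 for Dbp, 0.035 for Arntl, 0.13 for Rora, 0.23 for Hlf, 0.036 for Rorb, 0.058 for Ube3a, 0.22 for Snhg14, 0.012 for B230209E15Rik, -0.058 for Ndn, 0.024 for Rictor, -0.025 for Mbd3, -0.012 for Ramp3, -0.039 for Aldoc and -0.058 for C1qb. For sex in the atlas with tissue markers they were 0.012 for Dbp, -0.013 for Nr1d1, -0.078 for Nfil3, -0.026 for Zbtb16, -0.011 for Snrpn, 0.041 for Slc32a1 and 0.012 for Siglech, and with striatal markers alone 0.023 for Dbp, -0.063 for Nfil3, 0.047 for Slc32a1 and 0.0023 for Siglech.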

Other observations

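The tests of clock phase, of genes near N4bp2 and Sdad1 and all sample splits were chosen after the results were seen.

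Of the inhibitory neuron markers at ZT6, Pvalb, the calcium-binding protein of fast-spiking interneurons, was higher in calorimetry (0.72) and in males (0.58), and Reln, a secreted guidance protein of other interneurons, was lower in both comparisons (-0.51 and -0.50). Of the excitatory markers, Bcl11b (-0.37) and Syt6 (-0.47) were lower in calorimetry. In the atlas, males had more Ppargc1a, a coactivator of mitochondrial biogenesis (0.19), and Irs1, an insulin receptor substrate (0.24), and more of the clock output factor Hlf (0.19). Among imprinted genes, the light cycle effect was more positive in calorimetry for the long noncoding Meg3 (0.47) and more negative for the cell cycle inhibitor Cdkn1c (-0.39).

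Over the day, rhythmic genes peaked most often between ZT18 and ZT21, with 1201 of 7117 peaks, and least often between ZT12 and ZT15, with 718. Arc, a synaptic activity gene, stood at 72.2 ± 59.7 CPM at ZT6 and at 348.9 ± 131 CPM at ZT0 (n = 12). Among markers of other regions, Hdc, which makes histamine, of the hypothalamic list peaked at ZT1.13 (1.60-fold), Ramp3 of the thalamic list at ZT11.9 (1.34-fold) and the GABA transporter gene Slc6a13 of the meningeal list at ZT0.654 (1.71-fold).

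N4bp2 was lower in transgene carriers, Sdad1 was called only against the shared WT/WT libraries, and 1 hypothesis was a change that spreads to neighbouring genes on chromosome 5, as an insertion nearby may give. Of 64 other genes tested within 1 Mb, 0% had an unadjusted p under 0.05 in both WT/TG against WT/WT and HET/TG against HET/WT, which argues against a broad spread over that distance. An effect on these genes alone stays open.

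A shift of clock phase was a hypothesis for the light cycle effect on 21 core clock genes. In calorimetry females a single shift to a phase 9.5 h later on the atlas curves may account for it, as it gave 95% of the summed squared log2 change (95% interval 78.2 to 97.3, r across genes 0.97), where 14 comparisons of other atlas times with ZT6 gave 79.4% to 97.5% with errors of the shift of up to 3.1 h. The curves were fitted on those same libraries, so that range is no independent yardstick. At that shift the change of 7084 other rhythmic genes went with their atlas curves (r across genes 0.736, rho 0.755), although genes are not independent replicates. In running wheel females (2.2 h, 81.4%, interval 37.4 to 88), running wheel males (1.3 h, 63.2%, interval 16.5 to 82.5) and calorimetry males (2.1 h, 32.9%, interval 8.25 to 70.6) the intervals span the bound of 50%, which leaves a single shift open. Other rhythmic genes had r of -0.0446 to 0.162 and rho of 0.0794 to 0.148 in these.

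Library by library, mice on 11:11 were placed later than those on 12:12 by 9.02 h in calorimetry females (permutation p = 1e-05, the smallest that 100000 resamples give, adjusted p = 2e-05), by 2.31 h in running wheel females (permutation p = 0.00027, adjusted p = 0.00036) and by 1.34 h in running wheel males (permutation p = 0.00407, adjusted p = 0.00407). Calorimetry males on 11:11 spread over the circle (circular SD 6.5 h), with 7 of 15 over 6 h from 0 and 0 of 16 on 12:12. Their mean difference of 6.55 h (permutation p = 1e-05, adjusted p = 2e-05) is poorly defined and was 3.21 h without Per2. Searched within 6 h on either side, the differences were 4.83 h in calorimetry females, with 11 libraries within 1 h of the end of the window, 1.49 h in calorimetry males (permutation p = 0.054, adjusted p = 0.054), 2.24 h in running wheel females and 1.35 h in running wheel males. The difference between the sets was 1.36 h within 6 h (permutation p = 0.0822) and 5.97 h on the circle (permutation p = 1e-05), the last with the poorly defined mean of the calorimetry males. Atlas libraries taken 3 h after ZT6 were placed 2.95 h (females) and 3.22 h (males) later, and those taken 3 h before were placed at -4.43 and -5.18 h, so earlier shifts are overstated.

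Other splits of the same libraries were counted for each result. For HET/WT against WT/WT over all mice 1 of 35 splits gave as many calls, the real one with 8 (highest other 0), so chance can be excluded. The same holds with 1 of 35 for calorimetry females on 11:11 and 12:12 (4 and 4 calls, highest other 0), running wheel females (3 and 4, highest other 0) and running wheel males on 11:11 (4, highest other 0). For the number of calls alone, chance cannot be excluded for calorimetry males on 11:11 (9 of 35 splits, real 25, highest other 962) and 12:12 (4 of 35, real 85, highest other 177) or running wheel males on 12:12 (4 of 35, real 7, highest other 91). A split that calls several times the real count points to a structure among these males that the genotype labels do not follow. For the interactions of HET/WT with light cycle, sex and set the real count was 0, so that all 35 of 35 splits had to give as many (highest other 0, 2 and 0) and the splits say nothing.

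Among 25 splits each, 1 gave as many for WT/TG (real 3, highest other 0), HET/TG (9, highest other 2), light cycle (2383, highest other 2), the light cycle effect by set (1003, highest other 0), light cycle in calorimetry females (2319, highest other 0) and males (2544, highest other 964) and in running wheel females (52, highest other 1). The split of calorimetry males with 964 calls again points to a structure among them. In the same way 1 of 25 gave as many for calorimetry against running wheel (11713, highest other 4), sex at ZT6 (10948, highest other 0), rhythm (7117, highest other 24) and sex in the atlas (7069, highest other 4), so chance can be excluded for all of these. For the sex difference in rhythm 1 of 25 gave as many too (real 13, highest other 2), the smallest share these splits can give. That argues against chance for the count over all libraries, but the count fell to 0 without replicate number 2. For HET/TG against HET/WT 2 of 25 gave as many (real 2, highest other 5), which leaves the number of calls open. Chance for the genes called is argued against, as N4bp2 (-0.89) and Gm10800 (3.85) moved the same way in the separate libraries of WT/TG against WT/WT (-0.92, adjusted p = 2.09e-16, and 2.60, adjusted p = 1.89e-09). For light cycle in running wheel males the real count was 0, so that all 25 of 25 had to give as many (highest other 0).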
